A study of Homo sapiens with 6 samples.

How the data were processed

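Transcript levels were measured with Affymetrix U133 Plus 2.0 arrays in 2 stably transfected derivatives of Huh7, a human hepatocellular carcinoma line. Each line was hybridised to 3 arrays, and per the labels the 3 arrays of a line came from 1 total RNA preparation. The arrays of a line are therefore technical replicates. Every SD and p-value measures only the spread between arrays of 1 RNA, and every test compares 2 RNA preparations, not the conditions in general. With 3 arrays a line, the number of arrays limits the precision.

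The deposited values were probe set intensities on a linear scale, which per the submitters' processing notes came from RMA, a method that corrects background, normalizes arrays by quantiles and summarises the probes of each probe set. Its version, the form of its background correction and the step at which the values became whole numbers were not given in the sources used here. All deposited intensities were whole numbers from 3 to 11443, with a median of 9 on each of the 6 arrays. Rounding makes a step of 1 intensity unit a large share of a dim value: 42.0% of the 54675 probe sets never exceeded 8, and 5.09% had the same value on all 6 arrays. RMA also draws small fold changes of dim probe sets toward 0, and quantile normalization would remove a shift shared by most transcripts.

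Probe sets were named through the platform annotation, and symbols were updated through gene numbers in a reference gene table of GRCh38.p14, where 41043 probe sets found a current symbol. Of all probe sets, 41097 had 1 symbol, 1801 had several and 11777 had none given here, including most of the 62 Affymetrix control probe sets. No name was taken from a probe set with several symbols. The sources name no genome build, so no coordinates are given, and the gene table served only for names and for the order of neighbouring genes. One probe set stood for each of the 19775 genes tested, the one with the highest mean over the 6 arrays. Of these genes, 10520 had a mean intensity of at least 16. TCF7 and HSF2, fixed in advance as genes to report, are not analysed here, as are 89 members of the gene lists in all.

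Intensities were converted to log2 with no pseudocount and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test, no covariates), with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05 together with a change of at least 1.5-fold, and "rose" or "fell" is used only for called genes. Log2 differences are Huh7-S33Y minus Huh7-Vec, with limma's standard error (SE). Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the 32 lists that had at least 5 measured members. Camera asks whether the members shift relative to other genes. Camera with an estimated correlation, and fry, which asks whether the members move one way or change at all without setting them against other genes, were alternatives. Each list's median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. The lists, the rule for named genes, the tests and all alternatives except those said to be added were fixed before the data were examined.

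The genes named by rule were CTNNB1, the 12 largest rises and 12 largest falls among called genes whose arrays did not overlap between the lines, up to 4 called members of each list (or the 2 largest differences where none was called) and a fixed set of Wnt and liver genes. Open reading frame and LOC symbols were passed over. Genes named outside this rule were chosen after their values were seen.

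Groups of neighbouring genes were searched for after the data had been seen. The 8746 placed genes with a mean intensity of at least 32 were put in order, and the median log2 difference over windows of 15 genes was compared with 1000 shuffles of the gene order. A window past 0.405 in size, which 95% of the shuffles did not exceed, marked a run. Bootstrap intervals used 2000 draws.

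The procedure was tested on simulated data for Huh7-S33Y against Huh7-Vec over 19775 genes with 3 arrays a line. Among changed genes with a mean of at least 16, it recovered 87.3% of 2-fold and 93.4% of 3-fold changes. Among dimmer genes the recovery was 60.0% of 2-fold and 82.1% of 3-fold changes. No unchanged gene was called, and 0 of 100 random lists were called. The simulated noise was drawn independently for each gene, with the spread between arrays. These results therefore say nothing of false calls among genes that vary together, or of the spread between cultures. In the measured data 9 lists were called with the preset correlation and 0 with an estimated one. The alternatives were quantile normalization applied again, centring of each array on its median, filters on dim genes, another probe set or the mean of all probe sets for a gene, another variance model, a test against the fold minimum itself, the array number as a block, and leaving out each array. Other fold minimums and other list tests were also tried. After the data had been seen, a floor of 16 on all values and the removal of genes inside the runs were added. Figures were drawn with matplotlib 3.10.9.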

Results

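The comparison set Huh7-S33Y against Huh7-Vec. Huh7-S33Y carries beta-catenin with the S33Y substitution, which removes a phosphorylation site through which the protein is marked for degradation, and the submitters describe it as a line with high TCF activity. Huh7-Vec carries the pCI-neo vector. The question was how the transcripts of a liver cancer line change when TCF activity is raised. There were 6 arrays, 3 for each line, all 3 from 1 RNA preparation. The upper quartile of intensity lay between 44 and 47 on the 6 arrays. Arrays of a line correlated at r of 0.994 or more over probe sets, and arrays of different lines at 0.991 or less. The residual SD had a median of 0.091 on the log2 scale for genes with a mean of at least 16, and 0.16 for dimmer genes. The 3' to 5' signal ratio of ACTB, a sign of RNA integrity, was 1.82 to 1.90 on the Huh7-S33Y arrays and 2.02 to 2.10 on the Huh7-Vec arrays. The ratio of GAPDH was 1.03 to 1.09 in Huh7-S33Y and 1.023 to 1.035 in Huh7-Vec.

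CTNNB1, which encodes beta-catenin, was read by 3 probe sets. The brightest measured 768 ± 65.6 in Huh7-Vec and 809 ± 9.24 in Huh7-S33Y (SD, n = 3), a log2 difference of 0.079 (SE 0.066, adjusted p = 0.53) that was not called. A dimmer probe set fell by 0.64 on the log2 scale, from 104 ± 3.21 to 67.0 ± 6.25 (adjusted p = 0.0135 over all probe sets), with every Huh7-S33Y array below every Huh7-Vec array. The dimmest lay near the floor, at 14 in each line. Where these probes lie relative to the introduced sequence was not given in the sources used here, so their levels do not check whether the mutant transgene was expressed.

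In all, 660 of 19775 genes were called, 282 higher and 378 lower in Huh7-S33Y. Without the fold minimum 3039 genes passed the adjusted p, and 5510 had an unadjusted p below 0.05. The largest rise was that of L1CAM, a neural cell adhesion molecule, at 4.37-fold (33.7 ± 5.69 to 146 ± 2.52, log2 SE 0.13, adjusted p = 0.00185). As the mean of its probe sets L1CAM had a log2 difference of 1.28, below that of MAN1A1, which stayed between 1.96 and 2.03. MAN1A1, a Golgi mannosidase of N-glycan processing, rose 3.98-fold from 123 ± 3.46 to 490 ± 24.5 (adjusted p = 0.000644). ID4, an inhibitor of helix-loop-helix transcription factors, rose 3.86-fold from 11.3 ± 1.53 to 43.7 ± 4.62. The growth cone protein gene GAP43 rose 3.72-fold from 5.67 ± 1.53 to 20.7 ± 3.06, a gene for which rounding weighs on the fold. The drug-metabolising CYP2B6 (3.71-fold), the calcium-binding S100A6 (3.63-fold), CLIC6 (3.42-fold), the metalloprotease ADAMTS12 (3.31-fold), CADPS, a factor of vesicle exocytosis (3.26-fold), the liver glucose transporter SLC2A2 (3.21-fold), the kinase scaffold KSR1 (3.08-fold) and the G protein subunit GNB4 (3.03-fold) completed the 12 largest rises. CYP2B6 has near-identical relatives that its probes can also bind. Another probe set of CADPS, at 7.33 and 10, was not called (log2 0.44, adjusted p = 0.265), and CADPS and KSR1 were not called as the mean of their probe sets (log2 0.58 and 0.55). KSR1 has 1 other probe set with a mean of at least 16, and that one was not higher in Huh7-S33Y. As the mean of their probe sets ID4 (log2 0.77), GAP43 (0.73), S100A6 (0.93), CLIC6 (1.02), ADAMTS12 (0.92) and GNB4 (0.78) stayed called with smaller differences. CLIC6 and GAP43 were not called once values were floored at 16 (log2 0.43 and 0.36).

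The largest fall was that of FMO1, a flavin monooxygenase, from 45.3 ± 11.9 to 8.33 ± 1.53, or 5.38-fold (log2 -2.43, SE 0.23, adjusted p = 0.00462). FMO1 ended near the floor, and with values floored at 16 its log2 difference was -1.47, smaller in size than those of DEFB1 and TRIM31, which stayed at or past -2.22 and -2.05 under every alternative run for them. DEFB1, an epithelial antimicrobial peptide, fell 5.06-fold from 198 ± 12.4 to 39.3 ± 6.03, and TRIM31 fell 4.78-fold from 87.7 ± 7.57 to 18.3 ± 1.53. SERPINC1 (antithrombin) fell 3.84-fold from 207 ± 6.11 to 54.0 ± 2.65, SERPINA6 (corticosteroid-binding globulin) 3.38-fold from 158 ± 11.7 to 47.0 ± 5, and PLG (plasminogen) 3.37-fold from 48.3 ± 5.03 to 14.3 ± 1.53. PNPLA3, a lipid droplet enzyme of hepatocytes, fell 3.18-fold from 202 ± 10.4 to 63.3 ± 2.31. The linker histone gene H1-2 fell 3.83-fold, the guanine exchange factor VAV3 3.95-fold, NAT8B 3.93-fold, the anion exchanger SLC26A3 3.64-fold and the transcription factor ZIC2 3.49-fold. NAT8B has a near-identical relative, and its log2 difference was -0.97 with values floored at 16. As the mean of their probe sets VAV3 was at -1.19 and PLG at -0.75, still called. SLC26A3 and ZIC2 ended at 5.33 ± 0.577 each and were not called with values floored at 16 (log2 -0.27 and -0.21). Tested against the 1.5-fold minimum itself, 23 genes were higher and 22 lower, and a 2-fold minimum left 62 higher and 65 lower. With the mean of a gene's probe sets the counts were 183 and 231, and with quantile normalization applied again they were 336 and 331.

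Among Wnt/TCF target genes known from other tissues, 3 of 46 measured members rose and none fell. Besides L1CAM, these were DKK1, a secreted Wnt antagonist, which rose 2.31-fold from 315 ± 13.1 to 728 ± 51.6 (log2 SE 0.064, adjusted p = 0.00165), and LEF1, a partner of beta-catenin on DNA, which rose 2.07-fold from 18.7 ± 1.53 to 38.7 ± 3.79 (log2 SE 0.097, adjusted p = 0.00432). LEF1 was not called as the mean of its probe sets (log2 0.36). The other 43 members were not called. AXIN2, the feedback inhibitor most often used as a readout of the pathway, was at 19.3 ± 2.89 and 22 ± 1 (log2 0.20, SE 0.12, adjusted p = 0.387), and its log2 difference ran from 0.066 to 0.26 when 1 array was left out. NKD1 (log2 0.25, adjusted p = 0.53, or 0.079 to 0.45 with 1 array left out), SP5 (0.11, 0.398), CCND1 (-0.20, 0.0904) and CD44 (-0.28, 0.12) also missed the adjusted p. MYC (log2 0.12, adjusted p = 0.0473) and LGR5 (-0.38, adjusted p = 0.0325) passed it but not the fold minimum. NKD1 and CD44 lay below 16, where small changes are lost in rounding. The list did not shift relative to other genes (camera adjusted p = 0.894, or 0.925 with an estimated correlation). Its median log2 difference was -0.0028, at percentile 30.9 of matched random lists, while its mean was 0.058 and the test leaned up. By fry the members moved up on balance (adjusted p = 0.00791), a test without other genes as background. Of 20 Wnt feedback inhibitors 1, DKK1, rose (camera adjusted p = 0.897, leaning down with a mean of 0.026). Of 44 Wnt pathway components 1, the receptor FZD6, rose (log2 0.69, adjusted p = 0.0488; list adjusted p = 0.894). FZD6 had means of 9.33 and 15.0 and lost its call without any 1 of the 6 arrays (adjusted p 0.0519 to 0.142).

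**Figure D1:**
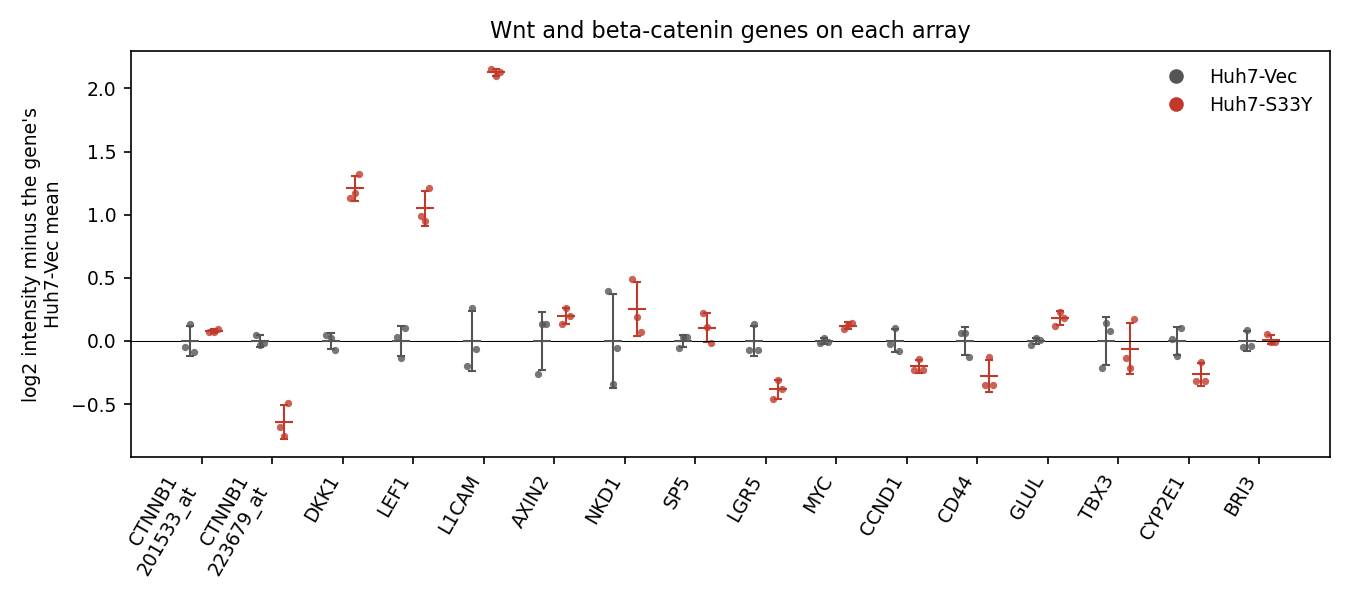
Each point is 1 array: log2 intensity minus the gene's mean over the 3 Huh7-Vec arrays, for 2 CTNNB1 probe sets (the brightest first) and 14 Wnt and beta-catenin genes, with bars for the mean and SD of 3 arrays. The Huh7-S33Y arrays stood apart upward for DKK1 (mean 1.21), LEF1 (1.05) and L1CAM (2.13), and by less for MYC (0.12) and GLUL (0.18), and downward for the second CTNNB1 probe set, LGR5, CCND1 and CYP2E1. For the first CTNNB1 probe set, AXIN2, NKD1, SP5, CD44, TBX3 and BRI3 the arrays of the lines overlapped.

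Liver targets of beta-catenin, the genes of the hepatocytes around the central vein, showed 0 called members among 27 measured (camera adjusted p = 0.798, or 0.815 with an estimated correlation, and 0.0331 by fry). GLUL, which encodes glutamine synthetase, was at 1099 ± 20 and 1244 ± 48.0 (log2 0.18, SE 0.038, adjusted p = 0.0399), below the fold minimum. CYP2E1 (log2 -0.26, adjusted p = 0.0843), TBX3 (-0.060, 0.843) and TNFRSF19 (0.50, 0.0633) were not called. CYP1A1 had a log2 difference of 0.54 (adjusted p = 0.0102) and was called only without Huh7-Vec array 3 (log2 0.61). The median of the list was 0.0096. BRI3, named in advance as a reported target of beta-catenin, was at 604 ± 33.2 and 608 ± 14.7 (log2 0.011, SE 0.049, adjusted p = 0.955). As 1 measured gene, that list was not tested. Of 18 genes of the periportal hepatocytes, 3 fell: the junction cadherin CDH1 (log2 -0.94, adjusted p = 0.00597), the histidine-degrading HAL (-0.84, 0.00185) and the urea cycle gene ARG1 (-0.68, 0.0197). The list itself did not shift (adjusted p = 0.457), with a median of 0.0044 and a mean of -0.099. ARG1 lost its call without Huh7-Vec array 2 or 3 or Huh7-S33Y array 3 (adjusted p 0.0659 to 0.0744). HAL and ARG1 were not called as the mean of their probe sets (log2 -0.27 and -0.086), and another probe set of ARG1 lay near the floor, at 4.67 and 5.33.

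Genes of mitosis were lower as a group in Huh7-S33Y. All 40 members were measured, 11 fell, none rose, and 38 had a difference below 0, with a median log2 difference of -0.46 that lay below every matched random list (camera adjusted p = 5.56e-19). The call was lost with an estimated correlation (adjusted p = 0.149). The motor protein CENPE fell from 78.3 ± 1.15 to 42.7 ± 1.15 (log2 -0.88, SE 0.031, adjusted p = 0.000983), the kinetochore protein CENPF from 459 ± 8.08 to 256 ± 16.5 (log2 -0.85, SE 0.053), the proliferation marker MKI67 from 296 ± 10.8 to 166 ± 4 (log2 -0.84, SE 0.039) and the spindle protein NUSAP1 from 440 ± 8.50 to 257 ± 9.82 (log2 -0.78, SE 0.038). The others that fell were FOXM1, PRC1, ASPM, UBE2C, CCNB2, CDK1 and PLK1, with log2 differences from -0.72 to -0.59. Another probe set of CENPF, near the floor at 5.67 and 4.67, gave -0.28 (adjusted p = 0.265). Genes of S phase and DNA replication shifted less: of 39 measured, 2 fell, the primase subunit PRIM1 (log2 -0.75, SE 0.043) and the ribonucleotide reductase subunit RRM2 (-0.66, SE 0.035), and 1 rose, the G1/S cyclin CCNE1 (0.69, SE 0.043, but 0.28 as the mean of its probe sets, adjusted p = 0.11). Their median was -0.16 (camera adjusted p = 0.000215, or 0.409 with an estimated correlation). The p53 target list had 0 called members of 24 (adjusted p = 0.597), its largest differences being those of PLK2 (log2 0.58, adjusted p = 0.0634, called without Huh7-S33Y array 1) and CCNG1 (0.52, 0.00491). MYC-activated ribosome biogenesis genes had 0 of 30 (adjusted p = 0.897), with WDR12 at 0.37 and NME1 at -0.29.

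Genes of the unfolded protein and amino acid stress response were higher as a group: 4 of 34 rose, none fell, 30 lay above 0, and the median was 0.23 (camera adjusted p = 3.79e-09, lost with an estimated correlation at adjusted p = 0.126). The 4 were genes of the endoplasmic reticulum. HSPA5, its main chaperone, rose 1.76-fold from 1419 ± 139 to 2494 ± 71.5 (log2 SE 0.077, adjusted p = 0.00454), CRELD2 rose 1.78-fold from 269 ± 13.6 to 479 ± 14.5, and the cochaperones DNAJC3 and DNAJB9 rose 1.58-fold and 1.56-fold. A dimmer probe set of DNAJB9, at 36 and 56, missed the adjusted p (log2 0.64, adjusted p = 0.0652). DNAJC3 lies in a run of neighbouring genes that were higher together, described at the end. None of the 21 measured heat shock response genes was called (adjusted p = 0.597), with HSPA4L at -0.42 and DNAJB4 at -0.57. Cytosolic ribosomal protein genes had 0 called members of 32, a median of 0.054 and an adjusted p of 0.0491. With an estimated correlation this was an adjusted p of 0.77, and the call was also lost without Huh7-Vec array 1 (0.248) or 3 (0.0587) or Huh7-S33Y array 2 (0.0811) or 3 (0.141). Their largest differences were those of RPS6 (log2 0.45) and RPS9 (0.32), which were 0.10 and -0.014 on probe sets without a shared-sequence suffix, that of RPS9 near the floor.

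In the NF-kB and acute phase list, 7 of 24 fell and none rose, with a median of -0.42 (camera adjusted p = 1.18e-06, lost with an estimated correlation at adjusted p = 0.126). Complement factor CFB fell 2.37-fold from 57.7 ± 5.69 to 24.3 ± 2.08, the NF-kB inhibitor TNFAIP3 2.23-fold from 125 ± 2.89 to 56.7 ± 8.08, the chemokine CXCL5 2.14-fold from 521 ± 40.1 to 243 ± 18.9 and CXCL1 1.67-fold from 147 ± 4 to 88.3 ± 11.9. CXCL8, CXCL2 and C1S also fell. CXCL1 lost its call without Huh7-Vec array 1 or 2 or Huh7-S33Y array 2 (adjusted p 0.0508 to 0.0532). Another probe set of CFB, at 17.3 and 17, did not differ (log2 -0.027), and another of CXCL5 lay near the floor, at 4.67 and 3.67. Of 39 interferon response genes 4 fell, IFITM3 1.90-fold from 543 ± 14.6 to 286 ± 14.6, IFITM2 1.80-fold, and the dim genes CXCL10 and IFI35, while the list did not shift (adjusted p = 0.253). IFITM3 and IFITM2 are near-identical in sequence and their probe sets have shared-sequence suffixes. CXCL10 and IFI35 lost their calls without any 1 of 5 arrays each (adjusted p 0.0528 to 0.0841 and 0.0559 to 0.082), CXCL10 keeping it without Huh7-Vec array 1 and IFI35 without Huh7-Vec array 2. Of 20 immediate early genes 2 rose, the transcription factor KLF4 (2.33-fold) and the phosphatase DUSP1 (1.52-fold, under the minimum at log2 0.54 both without Huh7-Vec array 1 and as the mean of its probe sets), with a list adjusted p of 0.897.

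Of 20 cholesterol synthesis genes 4 fell and none rose, with a median of -0.26 (camera adjusted p = 1.82e-05, or 0.409 with an estimated correlation). NSDHL fell 2.05-fold from 125 ± 7.81 to 61.0 ± 4.36, LSS 1.58-fold from 522 ± 6.56 to 331 ± 4.58, and LPIN1 and the sterol sensor INSIG1 1.63-fold and 1.51-fold. NSDHL lies in a run of neighbouring genes that were lower together. LPIN1 lost its call without any array but Huh7-S33Y array 3 (adjusted p 0.0539 to 0.0814), and INSIG1 without any Huh7-Vec array (adjusted p up to 0.0621) or without Huh7-S33Y array 1 (log2 -0.50). Of 19 fatty acid synthesis genes 4 fell, or 5 adjusted over the list alone with the transcription factor MLXIPL (log2 -0.67), and the median was -0.23 (camera adjusted p = 0.00151, or 0.149 with an estimated correlation). Besides PNPLA3 these were the triglyceride-forming DGAT1 (1.69-fold, 237 ± 4.73 to 140 ± 15.1), acetyl-CoA synthetase ACSS2 (1.63-fold) and fatty acid synthase FASN (1.60-fold, 322 ± 13.4 to 201 ± 14). FASN, LPIN1 and LSS were not called as the mean of their probe sets (log2 -0.37, -0.32 and -0.36). On probe sets without a shared-sequence suffix the list was not called (adjusted p = 0.658).

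Hepatocyte products changed in both directions. Of 37 secreted proteins 6 fell and 2 rose, with a median of -0.10 (camera adjusted p = 0.0491, or 0.472 with an estimated correlation). Besides SERPINC1 and PLG the genes that fell were APOH (1.94-fold, 1673 ± 20 to 861 ± 52), haptoglobin HP, ceruloplasmin CP and APOC3. A dimmer probe set of APOH, at 26.3 and 17, missed the adjusted p (log2 -0.64, adjusted p = 0.0698). Those that rose were fetuin AHSG (log2 0.77, adjusted p = 0.00122) and A1BG (12.3 ± 3.21 to 27.0 ± 3.00). The list lost its call without Huh7-Vec array 1 (adjusted p = 0.0892) or 2 (0.171) or Huh7-S33Y array 1 (0.128), 2 (0.0829) or 3 (0.0849), and A1BG without any array but Huh7-Vec array 2 (0.0608 to 0.0899). ALB (log2 0.078, SE 0.032, adjusted p = 0.209) and AFP (-0.055, SE 0.023, adjusted p = 0.201) were not called, and a dimmer probe set of ALB, at 94.7 and 71, gave -0.42 (adjusted p = 0.0919). None of 18 liver transcription factors was called (adjusted p = 0.894, median 0.013, mean -0.046), with FOXA1 at -0.41 and NR5A2 at -0.31. Of 34 drug and bile acid metabolism genes CYP2B6 rose, while the sulfotransferase SULT2A1 (2.19-fold) and the bile pigment exporter ABCC2 (1.77-fold) fell (list adjusted p = 0.597). None of 21 oncofetal and progenitor genes was called (adjusted p = 0.597), with NCAM1 at 0.54 and MDK at -0.56 (called without Huh7-Vec array 1, log2 -0.62). The value of NCAM1 rested on Huh7-S33Y array 2, without which it was 0.18, and another probe set near the floor gave -0.088.

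**Figure D2:**
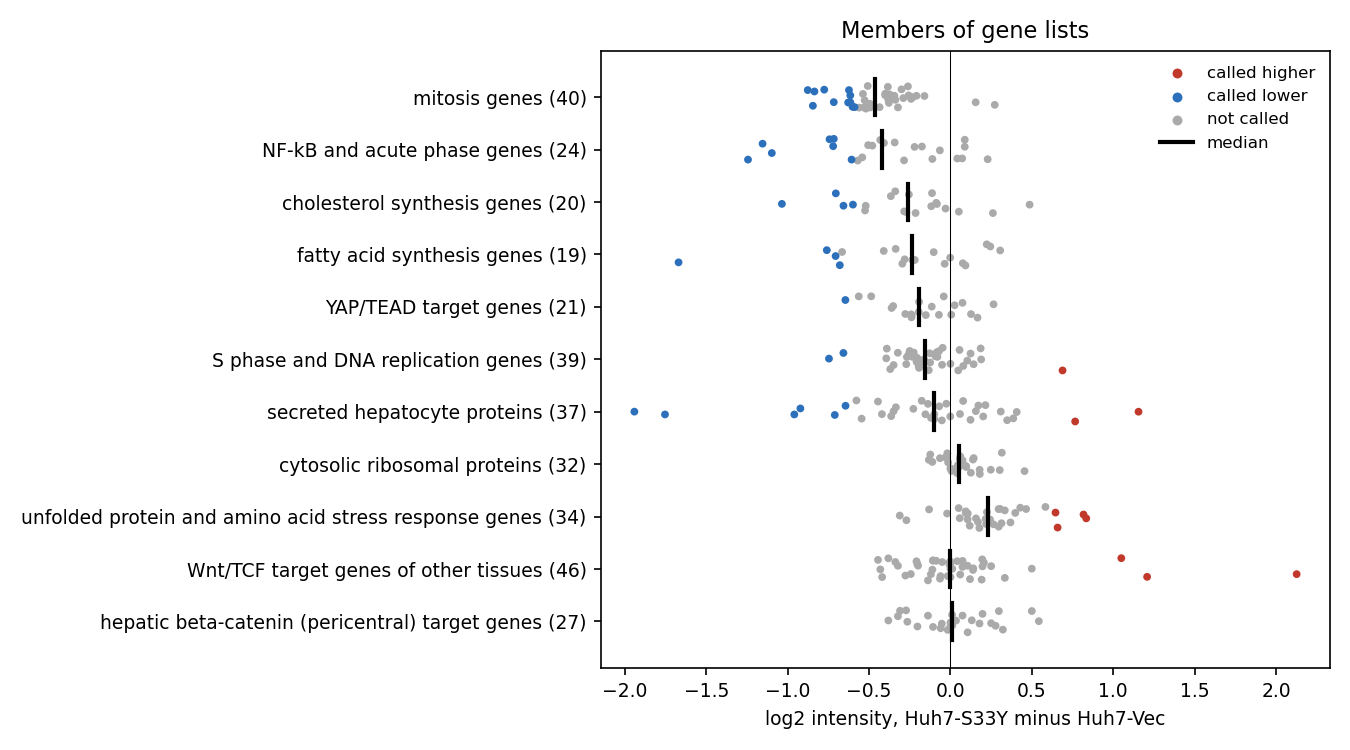
Log2 difference in intensity, Huh7-S33Y minus Huh7-Vec, of each measured member (points, number in brackets) of the 9 lists called by camera and of the Wnt/TCF and pericentral lists, with red for members called higher, blue for members called lower and a black bar for the median. The medians run from -0.46 for mitosis genes to 0.23 for the unfolded protein and amino acid stress response, and those of the Wnt/TCF and pericentral lists lie at -0.0028 and 0.0096.

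In other signalling lists few members were called. Of 27 TGF-beta and BMP targets 4 rose and none fell: ID4, the growth factor TGFB1 (2.15-fold, 53.7 ± 10.2 to 114 ± 9.29), ID3 (1.69-fold) and the matrix protein TGFBI (1.60-fold, 1586 ± 4.62 to 2538 ± 26.1). The list did not shift (adjusted p = 0.536), with a median of -0.041 and a mean of 0.16. TGFB1 was not called without Huh7-S33Y array 1 or 2 (adjusted p 0.0571 to 0.0596), nor as the mean of its probe sets (log2 0.58), and its other probe set lay near the floor, at 8 and 8.33. YAP/TEAD targets had a median of -0.19 over 21 members (camera adjusted p = 0.00323, or 0.441 with an estimated correlation), with 1 call, the fall of GADD45B (1.56-fold, but log2 -0.10 on a dimmer probe set at 24.7 and 23 and -0.44 as the mean of its probe sets, neither called). The Notch list had 1 call of 22, the rise of HES1 (1.80-fold, adjusted p = 0.0507 without Huh7-Vec array 3, with another probe set near the floor at 4.67 and 5.33) and did not shift (adjusted p = 0.894). Of 29 mesenchymal genes TGFBI alone rose (adjusted p = 0.179), and of 24 epithelial junction genes CDH1 alone fell, while CLDN6 (log2 0.76) was also called when adjusted over the list alone (list adjusted p = 0.404). Of 28 hypoxia and glycolysis genes GPI rose (1.73-fold, 614 ± 13.5 to 1065 ± 40, list adjusted p = 0.798). Of 33 oxidative phosphorylation genes NDUFS1 rose (log2 0.59, list adjusted p = 0.659), and lay under the fold minimum without Huh7-Vec array 2 or Huh7-S33Y array 1 or 3 (log2 0.53 to 0.58), on another probe set (0.49) and as the mean of its probe sets (0.37).

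Markers of other cell types did not shift as lists, but many of them lay near the floor. A mean of at least 16 was reached by 5 of 16 fibroblast and stellate cell markers and 2 of 14 endothelial markers. It was reached by 3 of 16 blood and immune cell markers and 8 of 15 cholangiocyte markers. Lists with few members above the floor could hardly shift, so the lack of a shift says little. The fibroblast and stellate cell list (16 measured, adjusted p = 0.894, with COL1A2 at log2 0.41 and COL3A1 at -0.23), the endothelial list (14, 0.932, median 0.027 and mean -0.041, with KDR at 0.30 and PECAM1 at -0.95, but 0.33 with quantile normalization applied again, and called lower with the lowest 25% of genes left out or with another variance model) and the cholangiocyte list (15, 0.768, with TFF1 at 0.56 and CFTR at -0.35) had no called member, and TFF1 was called without Huh7-Vec array 2 or Huh7-S33Y array 1 (log2 0.59 and 0.60) and with quantile normalization applied again. PECAM1 has 1 other probe set with a mean of at least 16, which was not lower in Huh7-S33Y. Of 16 blood and immune cell markers 2 rose, CD14 (2.70-fold, 50.7 ± 1.53 to 137 ± 1.53) and lysozyme LYZ (1.94-fold, 319 ± 22 to 619 ± 45.8), with a list adjusted p of 0.597. Of the 32 lists tested, 9 were called with the preset correlation and 0 with an estimated one, 19 were called by fry, and 22 had at least 1 called gene. Counts adjusted over the list alone equalled those over all genes for 30 of the 32. The ACTB 3' to 5' ratio also differed between the lines, being lower on each Huh7-S33Y array (1.82 to 1.90) than on any Huh7-Vec array (2.02 to 2.10). The GAPDH ratios overlapped, at 1.034 to 1.091 in Huh7-S33Y and 1.023 to 1.035 in Huh7-Vec. With 1 RNA preparation per line, a link of the lists to RNA integrity cannot be told from any other difference between the lines, and was not tested.

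Genes that changed were also grouped by position, in a search made after the data had been seen. There were 14 runs in which the window median of neighbouring expressed genes passed the threshold, 8 higher and 6 lower in Huh7-S33Y. Not every gene of a run shared its direction: in the weakest by this measure, from FARSB to CCL20, 7 of 11 expressed genes were higher (median 0.19), and from DSTNP2 to PTPN6 3 of 4 were lower. The strongest reached from MARCKS to ECHDC1, where 22 of 23 expressed genes were higher, with a median log2 difference of 1.01 (interquartile range 0.65 to 1.11) and 21 genes called. MAN1A1 lies in it. Its largest window median, 1.03, was above that of each of 1000 shuffles of the gene order, the highest of which was 0.566. In the run from VMA21 to FAM3A 19 of 20 expressed genes were lower (median -0.64) and 11 were called lower. The exception there was L1CAM, which rose. The run from HEBP1 to PKP2 was lower over 39 of 43 expressed genes (median -0.52), and the runs from WDR55 to DELE1 (0.56), from NAB1 to CFLAR (0.45), from DNAJC3 to ARGLU1 (0.49) and from SEC62 to ZMAT3 (0.44, with SLC2A2) were higher. ZIC2 fell within the run from DNAJC3 to ARGLU1. Runs held 447 genes, 2.26% of those tested, and 83 of the 660 called genes (12.6%), an excess that follows in part from how runs were chosen. Without the genes of the runs, 235 genes were higher and 341 lower.

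**Figure D3:**
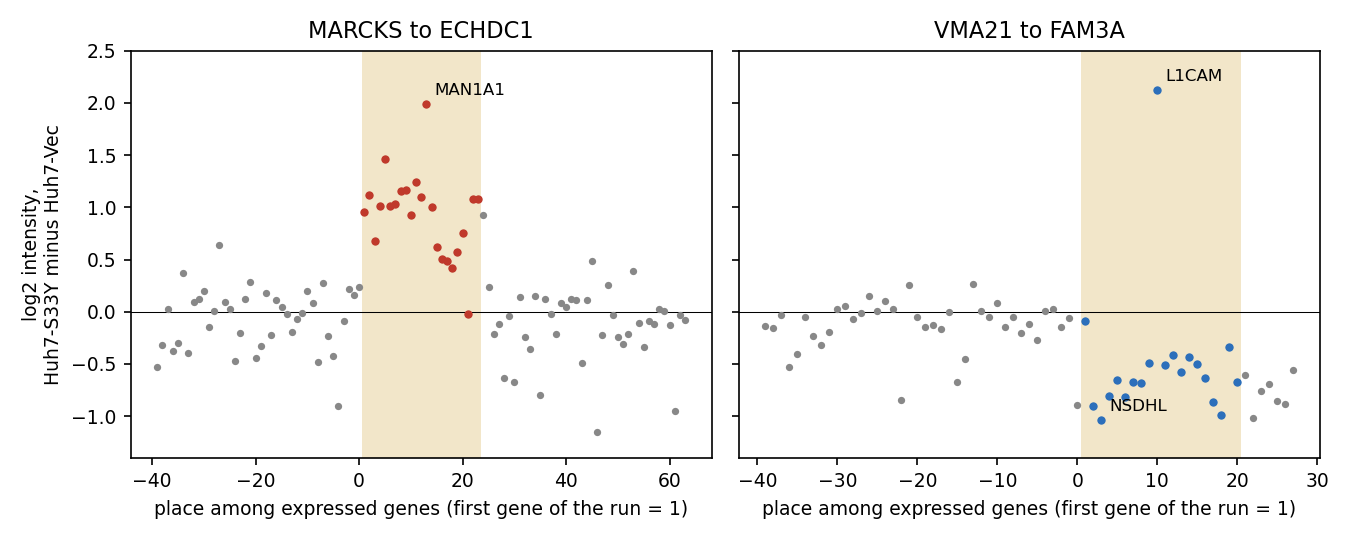
Log2 difference in intensity, Huh7-S33Y minus Huh7-Vec, of expressed genes in their order on the chromosome (x axis, place counted from the first gene of the run), for the run from MARCKS to ECHDC1 and the run from VMA21 to FAM3A with their neighbours. Coloured points on the shaded band are the 23 and 20 expressed genes of the runs, with medians of 1.01 and -0.64, grey points are neighbours outside, and L1CAM stands at 2.13 against the other genes of its run.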

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

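The tests of gene order, copy number, probe sets in runs, mitosis genes in runs and growth state named here were chosen only after the results they bear on were seen.

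Probe sets with no gene given here, and probe sets with several, were left out of the comparison of genes, and both held differences between the lines. Of 11721 probe sets with no gene given, other than Affymetrix controls, 27 were called higher and 152 lower in Huh7-S33Y. The largest of these differences was that of a probe set that went from 204 ± 16.3 to 34.3 ± 5.51 (log2 -2.58, adjusted p = 0.0017), followed by another that went from 32.7 ± 8.15 to 7.33 ± 0.577. Among those that rose, the one with the largest rise went from 46.0 ± 3.61 to 135 ± 4.16. Of 1801 probe sets with several genes, 11 were called higher and 46 lower. Among the 62 Affymetrix control probe sets, 3 were called higher.

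For the 660 called genes, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many genes, namely the real one, and the highest count among the other splits was 0. With 10 splits no share below 0.1 can be reached, so the splits alone cannot exclude chance. They also say nothing of the spread between cultures, since each line was represented by 1 RNA preparation.

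Runs of neighbouring genes that shifted together were the first pattern weighed. The order of the genes by chance is argued against: 0 of 1000 shuffles gave a window median as large as 1.03. In runs found on every other expressed gene, 82.2% of the 73 genes held out lay on the run's side (95% exact binomial interval 71.5 to 90.2), an interval that holds the 80% set as the bound for a difference in copy number, so that difference remains a hypothesis. Probes that also bind related genes are argued against as the whole cause, since of the held-out genes 49 had gene-specific probe sets and 85.7% of these lay on the run's side (72.8 to 94.1). The held-out genes came from 12 runs, and genes of the same run are not independent. Both intervals are therefore too narrow, and the argument from probe sets is weaker than its interval. No DNA was measured, so a gain or loss in one line may not be told from regulation of a whole domain, and 80 of the 83 called genes inside runs went with their run, as the choice of runs favours, while L1CAM, ZIC2 and MCC went against theirs.

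The lower level of mitosis genes was the second pattern. Their place in the runs is argued against as its cause, since 1 of the 40 members lay inside runs (2.5%, 95% exact binomial interval 0.0633 to 13.2), and that member, ECT2, was at 0.27 on the log2 scale. Runs held 2.26% of all genes, so a share that low was likely beforehand. The 40 members are the whole list and not a sample, so the argument rests on the count and not on the interval. The list kept its call without the genes inside the runs. A different growth state of the cultures at harvest is a candidate explanation, because genes of S phase and DNA replication were lower too, with a median of -0.158 (95% interval -0.208 to -0.0804). These genes are not independent, so the interval is too narrow. In that list PRIM1 and RRM2 fell, while CCNE1 rose (log2 0.69). A different growth state cannot be told apart from an effect of the mutant beta-catenin, as each line gave 1 RNA preparation. That effect, the biological explanation the design names, stays open and untested.

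The Wnt/TCF target list, which did not shift although the line was described as having high TCF activity, was the third pattern. The 30 members with a mean of at least 16 had a median of 0.00283 (95% bootstrap interval -0.116 to 0.14). That interval lies below the 1.5-fold rise set in advance as the bound, so their median was not shifted up by that much. The bound was lenient, as even the called list of mitosis genes had a median of -0.46. These members were chosen for a mean of at least 16, so they cannot decide whether dim probe sets hid a shift of the list. A smaller shared rise within the interval is not excluded, and for the dimmer members the reason stays open. Members went both ways, with L1CAM, DKK1 and LEF1 called higher and LGR5 (-0.38) and SALL4 (-0.45) below 0, so the median says nothing of single genes. Whether the targets of beta-catenin in Huh7 are other genes, or whether the pathway was already active in Huh7-Vec, was not tested.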

How the results depend on the processing

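Results were computed again under each alternative that applied to them and in which their gene or list was still measured, which was 15 to 17 alternatives for a gene and 18 to 19 for a list, and a floor of 16 and the removal of genes inside the runs were added after the data had been seen. Of the gene values, 1575 kept their call and sign, 138 lost a call, 8 gained one and 20 changed sign. Of the list values, 514 stayed, 29 lost a call, 32 gained one and 31 changed sign. The cause of the sign changes and of the lost calls was not tested unless given here. One RNA preparation per line was measured throughout, so no alternative reaches the spread between cultures.

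With camera's correlation estimated instead of preset, all 9 calls were lost: mitosis 0.149, unfolded protein and amino acid stress 0.126, NF-kB and acute phase 0.126, cholesterol 0.409, fatty acid 0.149, S phase 0.409, YAP/TEAD 0.441, secreted proteins 0.472 and ribosomal proteins 0.77 (adjusted p). By fry the Wnt/TCF list (0.00791, or 1.67e-05 for change in either direction) and the pericentral list (0.0331, or 7.77e-07) were called and the ribosomal list was not (0.0531). Wnt pathway components (0.00392) and Wnt feedback inhibitors (0.00641) were called by fry too, the feedback inhibitors higher where camera leaned down. Hypoxia genes (0.455) were not called and also leaned the other way from camera. For change in either direction 22 lists gained a call by fry. Among them were fibroblast and stellate cell markers (0.0139) and blood and immune cell markers (2.3e-06), while endothelial markers (0.226) stayed uncalled. The values for either direction therefore do not set the Wnt/TCF and pericentral lists apart from other lists.

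Called genes numbered 1407 higher and 1632 lower with no fold minimum, 62 and 65 with a 2-fold minimum, 23 and 22 when tested against 1.5-fold, and 183 and 231 with the mean of a gene's probe sets. That mean gave CTNNB1 -0.19 on the log2 scale, since it joins a probe set that fell with one that did not, and the secreted list 0.0931. Sign changes under it were BRI3 -0.018, CD44 0.011, COL3A1 0.0039 and TBX3 0.034, with the Wnt feedback list at 0.936, liver transcription factors at 0.922 and endothelial markers at 0.873. On probe sets without a shared-sequence suffix the fatty acid list (0.658) and the ribosomal list (0.351) lost their calls. The sign changed for ALB -0.42, ARG1 0.19, BRI3 -0.25, COL1A2 -0.12, NCAM1 -0.088, RPS9 -0.014 and TBX3 0.030, and for the Wnt feedback list (0.927), epithelial junctions (0.927) and endothelial markers (0.843). The other probe sets of ARG1, BRI3, COL1A2, NCAM1 and RPS9 had means below 9, where 1 unit of rounding sets the sign.

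Quantile normalization applied again called 336 genes higher and 331 lower, so the excess of lower genes was not kept. It gave the ribosomal list 0.311 and changed the sign of BRI3 (-0.0054), PECAM1 (0.33), the MYC list (0.969) and endothelial markers (0.826). PECAM1 has 1 other probe set with a mean of at least 16, which was not lower in Huh7-S33Y. Whether that probe set stood for PECAM1 under this alternative was not tested, so its sign change cannot be credited to scaling. With genes below the median left out, the secreted list had 0.0909 and the ribosomal list 0.117, and Wnt components (0.839) and the MYC list (0.839) changed direction. With the lowest 25% left out these were 0.0713 and 0.112, and the Wnt feedback list (0.868) and Wnt components (0.941) changed direction. A floor of 16 gave the secreted list 0.0506. Without genes inside runs the Wnt feedback list had 0.992 and the other direction.

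With the array number as a replicate block, 189 genes were higher and 246 lower. The secreted list had 0.0732, and the Wnt/TCF list (0.993), immediate early genes (0.993) and endothelial markers (0.993) changed direction. Arrays of the lines share only a number: deviations of arrays with the same number correlated at 0.0833, 0.00565 and -0.11, and none correlated best with its own number, so the block takes degrees of freedom and the lost calls are not weaker effects.

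Leaving out each array in turn gave the secreted list adjusted p from 0.00535 to 0.171, the ribosomal list 0.00354 to 0.248 and mitosis 5.22e-18 to 1.58e-16, with 206 to 274 genes higher and 281 to 391 lower. Values that changed sign ran from -0.013 to 0.057 (BRI3), -0.40 to 0.028 (COL3A1) and -0.18 to 0.017 (TBX3). Lists that changed direction had adjusted p from 0.786 to 0.998 (immediate early), 0.619 to 0.978 (endothelial), 0.699 to 0.998 (liver transcription factors), 0.69 to 0.98 (MYC), 0.464 to 0.998 (blood), 0.639 to 0.999 (Notch) and 0.558 to 0.998 (fibroblast).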

Other observations

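The gene families named here, and their tests, were chosen after the data had been seen. In each family only members with a mean of at least 16 were counted. Replication-dependent histone genes were lower in Huh7-S33Y. Of 10 with a mean of at least 16, 6 fell, 9 lay below 0 and the median log2 difference was -1.11, under each scaling tried (camera adjusted p = 3.55e-07 over 5 families, or 0.095 with an estimated correlation). H2BC12 fell from 1463 ± 18.9 to 692 ± 16.7 (log2 -1.08, SE 0.029), H2BC5 from 635 ± 5.77 to 237 ± 6.56 (log2 -1.42, SE 0.030) and H2AC6 from 218 ± 2.52 to 99.0 ± 5.57 (log2 -1.14, SE 0.047), while H3C8 was at 29.3 ± 2.08 and 30.7 ± 3.22. Of the 10 probe sets 7 have a shared-sequence suffix, so members of the family cannot be read apart, and the 3 without one had a median of -1.08. Such probe sets are not independent, and the family was chosen after the data had been seen. Its adjusted p at the preset correlation is therefore too small. Most transcripts of these genes end without a poly(A) tail, and arrays primed from the tail read the remainder.

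Of 7 S100 genes, which encode small calcium-binding proteins, 3 rose: S100A6, S100A14 (14.7 ± 0.577 to 27.3 ± 4.62) and S100A16 (110 ± 4.58 to 166 ± 5.20). S100A10 (log2 -0.38, adjusted p = 0.011) and S100A11 (-0.41, 0.0262) lay below 0 and under the fold minimum, and the median was 0.42 (0.45 with quantile normalization applied again). Of 7 metallothioneins MT1M rose (57.0 ± 2.65 to 150 ± 5.86, log2 1.39), and the other 6 had log2 differences from -0.056 to 0.18, on probe sets with shared-sequence suffixes. Of 17 serpins SERPINE2 rose (393 ± 11 to 751 ± 28), and SERPINA6, SERPINB9 and SERPINC1 fell. SERPINE2 lies inside the run from FARSB to CCL20, where 7 of 11 expressed genes were higher and CCL20 was at -0.29. All 4 protocadherin beta genes measured above 16 were higher (median 0.62, 3 called) and lie in 1 run of neighbouring genes that were higher together.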
